A study of Mus musculus with 3 samples.

How the data were processed

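Lung cells sorted by flow cytometry were loaded on a droplet system with a target of 10000 cells per library, and libraries were made with version 2 of the 3' chemistry, per the labels. The barcodes appear to begin as those of a later version do, and no barcode list was at hand to check this, so the version stays in doubt. Wildtype cells of 2 samples, knockout cells of 3 and ligation cells of 3 were each pooled before library preparation, per the labels, so each group is 1 library and nothing ties a cell to its animal. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) for 55359 genes and each barcode. The submitters' processing notes name STARsolo 2.7.9a, Seurat 4 and the genome build mm39, without their role, and the rule by which the authors kept barcodes is not given in the sources used here. Every deposited barcode held at least 500 UMIs. Gene symbols and versioned identifiers are those of the deposited files. The annotation at hand is of another build, so no coordinates are given.

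Groups, comparisons, gene lists, filters, the rule for named genes and the alternatives were chosen before the data were examined, apart from those marked as added later. Cells with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs passed, which left 4477, 5427 and 7431 of 6434, 7594 and 9842 barcodes of the wildtype, knockout and ligation libraries. Doublets were scored per library with the Scrublet method of scanpy, and the barcodes with the highest scores, 0.8% per 1000 barcodes, were removed: 331, 461 and 775 barcodes, or 5.14%, 6.07% and 7.87%. Some of these also failed the filters, so 4202, 5007 and 6745 cells stayed. Median depth over all barcodes was 10336.5, 5840 and 4984.5 UMIs. A share of 0 cells is given with the upper limit set by 3 counts, and a ratio against 0 UMIs would be a bound against 3 UMIs.

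The libraries were clustered together without integration, because integration can also remove the difference between groups. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 gave 22 clusters. Mitochondrial and ribosomal genes, Xist, Tsix, Y-linked genes and every gene of the lists were kept out of the variable genes. Genes named Gm and a number, Rn18s, Malat1 and Lars2 were kept out too. All others could take part, so their ratios between clusters of 1 library are not given as results. AT1-like and AT2-like cells lay mostly in different clusters in the 3 libraries. Ratios of unlisted genes such as Hopx between libraries are therefore not independent of the clustering. A cluster was named from the 15 marker lists when the mean log2 ratio of its best list to all other cells was at least 1 with 10 CPM added, lay 0.6 above that of the next list and rested on at least 3 markers. Its 10 leading genes also had to hold more markers of its own list than of any other, unless they held none of any list. These bounds for names were set after the clusters had been seen. Cells with Xist and no Y-linked UMIs (Ddx3y, Uty, Eif2s3y, Kdm5d) were read as female, and the reverse as male.

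Raw UMIs were summed per library over AT1-like and over AT2-like cells, and CPM are these counts scaled by the total of the class, computed here from the deposited counts. Ratios carry exact conditional 95% intervals, levels exact Poisson and shares exact Clopper-Pearson intervals; all cover counting error only. With 1 library per group no test between groups was possible, and no p-value or count of changed genes is given. Named genes, per class and comparison, were the 12 with the highest and the 12 with the lowest ratio among genes with at least 200 UMIs and 50 CPM in the higher library. Genes with predicted names, mitochondrial, ribosomal and sex-linked genes and markers of non-alveolar cell types were left out of these. Up to 4 members of each list with the largest ratios, any AT1 or AT2 marker and Cdc42 could be named as well, and the text gives part of the genes the rule allows.

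The 19 pathway lists and 15 marker lists were written from general knowledge of lung epithelium. A member was measured when it had at least 50 UMIs in the library with more of them, counted as higher or lower from 1.5-fold on, and a list needed 3 measured members for a median. Each median was placed among those of 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries, and its counting interval came from 1000 Poisson draws. The correlation of knockout and ligation ratios was set beside 100 simulations without effect. For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs. The free RNA share of a library was estimated from 6 AT2 genes in its ciliated-like cells relative to the profile of all its barcodes, as 3.38%, 2.12% and 3.0% from 211, 1984 and 1406 cells, and used only in an alternative.

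The ratios were tested on simulated counts in which 200 genes of each comparison were given known folds of 1.5, 2 or 4. These were independent Poisson counts, on which the intervals rest, so coverage near 95% follows by construction. They held no variation between cells, animals or libraries, so this checks the computation alone. In knockout against wildtype AT1-like cells (9555 genes) intervals held the true fold for 97.0% of 67 genes at 1.5-fold and 95.5% of 66 at 4-fold. In ligation against wildtype AT1-like cells (10396 genes) they did for 95.5% of 67 and 93.9% of 66. In AT2-like cells the lowest share was 90.9% of 66 genes (4-fold, knockout against wildtype, 11360 genes) and the highest 98.5% of 67 (1.5-fold, ligation against wildtype, 11329 genes), where 97.0% had the right sign.

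Besides the main settings, these were run: clustering at resolution 0.5 and 2.0, with the lists kept, with each library alone and with thinned cells; no cell filter, and a strict one of 1000 genes, 2000 UMIs and 5% mitochondrial UMIs; doublets kept; TMM factors of edgeR and size factors of DESeq2 on the class sums; the 20 most abundant genes left out of the total; a pseudocount of 1 CPM with no minimum; cells weighted equally; free RNA subtracted; thinning to 1000 UMIs or none; and other bounds on lists, folds and correlations. Under another clustering, a cluster took the class that most of its cells had in the main one. Joining clusters 1 and 7 to the AT1-like class, using cells of 1 sex, and asking for 6 AT1 genes were added after the data were seen. In ciliated-like and secretory-like cells some single genes and the gene lists were compared between libraries after the data were seen, without random lists or other settings apart from free RNA for Hopx, and other classes were not compared; 1 of the pathway lists and some single genes are left out of the text, and the reads were not analysed here. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.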

Results

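Lung cells of adult mice were sorted by flow cytometry and sequenced with droplet-based 3' single-cell RNA-seq, in 1 library for each of 3 groups. All animals carried Hopx-creERT2, a tamoxifen-dependent recombinase driven from the Hopx locus, and a yellow fluorescent reporter that marks cells in which it acted and their descendants. The wildtype library pooled 2 samples of epithelial cells from mice aged 8 to 10 weeks. A second library pooled 3 samples of lineage-traced mice of the same age whose floxed Cdc42 alleles are deleted by this recombinase; it is called the knockout library here. The third pooled 3 samples of lineage-traced mice aged 14 to 16 weeks after ligation of the left bronchus, which closes the airway of the left lung. Cdc42 organises actin and cell polarity. Alveolar type 1 (AT1) cells are the thin cells through which gas is exchanged, and alveolar type 2 (AT2) cells make surfactant and can give rise to AT1 cells.

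The wildtype, knockout and ligation libraries held 6434, 7594 and 9842 barcodes with 69663573, 54502021 and 60546700 UMIs in all, and 4202, 5007 and 6745 cells passed the filters. The most abundant transcript took 19.7% of wildtype UMIs (Rn18s, ribosomal RNA), 15.8% of knockout UMIs (Scgb1a1, the club cell secretoglobin) and 7.74% of ligation UMIs (Rn18s). Cells with Y-linked and no Xist UMIs numbered 2741, 1250 and 1117, and cells with Xist and no Y-linked UMIs 14, 1809 and 3047, so the pools differed in sex. All pools held male cells, so groups could also be compared within male cells alone. Age (for the ligation library), sort, animals and group cannot be separated with 1 library per group, and no difference between libraries has a replicate check. Values in parentheses after a level, fold or share are 95% intervals for counting error alone.

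Cdc42 (ENSMUSG00000006699.18) was measured first. In AT1-like cells its level was 713 (698 to 728) CPM (counts scaled by the total of the class) in the wildtype, 740.0 (719.6 to 761) in the knockout and 676 (664 to 688) in the ligation library. In AT2-like cells it was 167 (163 to 171), 243 (234 to 253) and 212 (199 to 226) CPM. The deleted exon is not given in the sources used here and the assay reads 3' ends, which can lie outside the deleted part, so these levels check neither the deletion nor the label.

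The first question was which epithelial classes each sort held, and how alveolar cells divided between AT1-like and AT2-like. AT1-like cells, called from markers such as Ager, Aqp5 and Rtkn2, made up 24.4% (23.1 to 25.7) of wildtype, 15.4% (14.4 to 16.4) of knockout and 37.5% (36.3 to 38.6) of ligation cells. AT2-like cells, called from surfactant genes such as Sftpc and Sftpb, made up 52.9% (51.4 to 54.4), 19.2% (18.1 to 20.4) and 5.69% (5.15 to 6.27). Among AT1-like and AT2-like cells together, AT2-like cells were 68.4% (66.8 to 70.0) in the wildtype, 55.5% (53.2 to 57.9) in the knockout and 13.2% (12 to 14.5) in the ligation library. Ciliated-like cells held 5.02%, 39.6% and 20.8%, and secretory-like cells 1.36%, 8.77% and 2.52%. Mesenchymal-like cells numbered 28, 32 and 78 and endothelial-like cells 19, 35 and 43. Proliferating-like cells numbered 9 in the wildtype and 32 in the knockout, while 0 of 6745 ligation cells were so named, which allows a share of up to 0.0445%. The sample labels name epithelial cells for all 3 libraries, and the design text names epithelial cells for the wildtype library and lineage-traced mice for the others; the gates are not given in the sources used here, and the sort can set these shares.

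**Figure D1:**
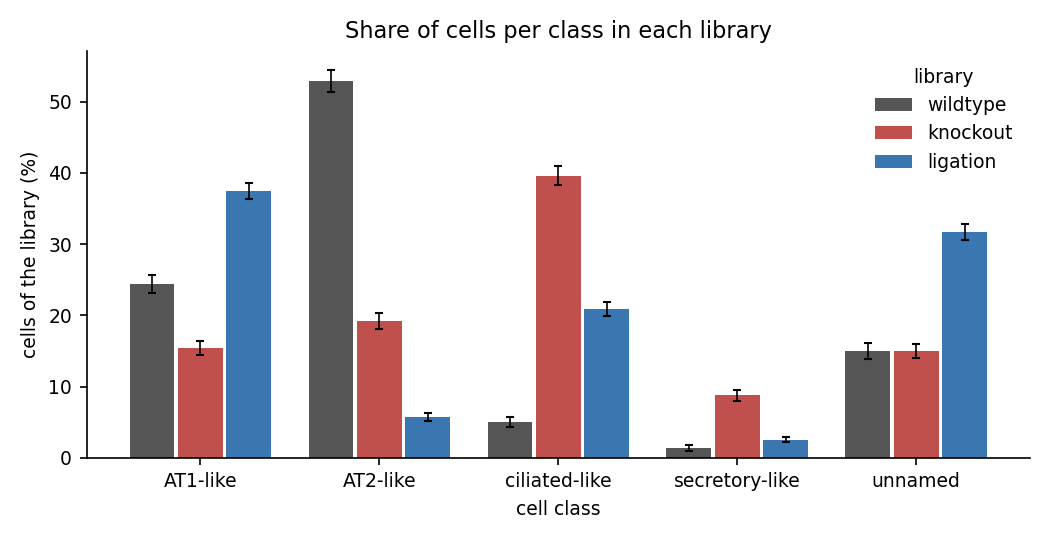
Share of cells in 5 classes (vertical axis, percent of the cells of a library) in the wildtype, knockout and ligation libraries, with exact 95% binomial intervals for counting error as error bars and 1 library per bar. The AT2-like bar is highest in the wildtype library (52.9%) and the AT1-like bar in the ligation library (37.5%).

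Different clusters held the same class in the 3 libraries. AT1-like cells lay mostly in cluster 6 in the wildtype, in cluster 9 in the knockout and in clusters 3, 8 and 14 in the ligation library. AT2-like cells lay mostly in cluster 0 in the wildtype and cluster 5 in the knockout, and in clusters 13, 0 and 5 in the ligation library. Immune or stress genes were among the leading genes of some named clusters: Ifit3 in cluster 3, H2-Eb1 and H2-Ab1 in cluster 5, H2-Ab1 and H2-Aa in cluster 13, and Hsph1 in the ciliated-like cluster 2. The other 5 clusters stayed unnamed under naming thresholds set in part after the data were seen. Cluster 1, with median depths of 2056, 1555 and 1432 UMIs, held 7.66%, 14.2% and 15.7% of wildtype, knockout and ligation cells. Cluster 7 held 0.167%, 0.0200% and 13.7%, cluster 12 held 7.09%, 0.559% and 0.400%, and cluster 21 held 0.0714%, 0.200% and 0.252%. Cluster 16 held 0.0200% of knockout and 1.62% of ligation cells and 0 of 4202 wildtype cells, which allows a share of up to 0.0714%. With clusters 1 and 7 joined to the AT1-like class, an alternative added after the data were seen, the AT2-like share of both classes was 62.1%, 39.4% and 7.84%.

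The comparison of AT1-like cells between the knockout and wildtype libraries asks how AT1-like cells differ between these mice; the origin of single cells is not known here. Genes of the transitional list, a set seen in cells between the AT2 and AT1 states, were higher in the knockout: all 14 measured members were at least 1.5-fold higher, with a median log2 ratio of 1.85, above all 10000 random lists. Outside the alveolar classes, a comparison added after the data were seen, members were also at least 1.5-fold higher in the knockout, 15 of 16 (median 1.38) in ciliated-like and 15 of 15 (median 1.58) in secretory-like cells, as they were in the ligation library against wildtype, 12 of 15 (median 1.2) and 13 of 13 (median 1.90). Scgb1a1 alone stood at 607740, 632090 and 487370 CPM in wildtype, knockout and ligation secretory-like cells. A lower level of such a gene raises the CPM of all others by construction, and no other scaling was run in that class. In AT1-like cells Areg, an EGF receptor ligand, was 38.2-fold (29.6 to 50.1) higher. Sfn, the 14-3-3 sigma protein, was 35.4-fold (30.5 to 41.3) higher, at 516 against 14.6 CPM. Plaur, the urokinase receptor, was 9.45-fold (8.10 to 11.1) higher and Clu, a secreted chaperone, 7.15-fold (6.33 to 8.09) higher. Among single genes with large ratios, Tnn, tenascin N, was 38.7-fold (29.3 to 52.1) higher, Phlda1 8.34-fold (7.73 to 9.02) higher and Thbs1, thrombospondin 1, 5.44-fold (5.01 to 5.91) higher.

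Hopx (ENSMUSG00000059325.15), a homeobox cofactor and AT1 marker that is not in the AT1 list, was 6.09-fold (5.96 to 6.22) lower in knockout AT1-like cells, at 1446 against 8805 CPM. The recombinase sits in this locus in all 3 groups. Chst8 was 23.6-fold (14.7 to 40.8) lower and the clock repressor Nr1d1 5.80-fold (4.59 to 7.41) lower. The AT1 list as a whole had 4 of 21 members higher and 2 lower, with a median of -0.15 (percentile 0.07 of the random lists). Ndnf, Igfbp2 and Itgb6 were 2.09-fold, 2.01-fold and 2.03-fold higher, Rtkn2 was 1.81-fold lower, and Ager stood at 19128 against 21225 CPM. AT2 list members were lower, 18 of 21, with a median of -2.12: Slc34a2 was 11.2-fold (8.61 to 14.8) lower, Scd1 7.79-fold (6.50 to 9.42) lower and Sftpc 2.46-fold (2.41 to 2.51) lower. In ciliated-like cells the AT2 median was -1.98. Ciliated markers were higher (6 of 7 members, median 2.88), as were secretory markers (5 of 7, median 1.40). These marker ratios ran in the direction of the class shares of the libraries, where AT2-like cells were 52.9% and 19.2% and ciliated-like cells 5.02% and 39.6% of wildtype and knockout cells. With free RNA subtracted, the AT2, ciliated and secretory medians were -2.00, 2.19 and 2.94, and the log2 ratio of Sftpc was 0.15.

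Actin and focal adhesion genes were higher for 9 of 25 members and lower for 0 (median 0.39, percentile 99.9), among them zyxin (Zyx, 2.87-fold, 2.34 to 3.52), filamin A (Flna, 2.55-fold, 2.32 to 2.81), ezrin (Ezr, 2.26-fold, 2.15 to 2.37) and Tpm4 (2.23-fold, 2.09 to 2.38). This list was also higher in ciliated-like (median 0.56) and secretory-like (median 0.29) knockout cells. Cdc42ep1, a Cdc42 effector, was 10.1-fold (6.88 to 15.4) higher. Of the unfolded protein list, 5 of 15 members were higher (median 0.42), including the chaperone Hspa5 (2.04-fold) and Manf (1.94-fold). The immediate early and heat shock list had 9 higher and 1 lower of 22 (median 0.40), beside medians of 0.24 in ciliated-like and 0.64 in secretory-like knockout cells. In AT1-like cells Atf3 was 3.38-fold higher and Ier2 2.64-fold lower. Against wildtype male cells 11 members were higher in knockout male cells (median 0.53) and 1 in knockout cells with Xist (median 0.038). Id1 and Id3, targets of BMP signalling, were 2.42-fold and 2.64-fold lower, and the tight junction gene Cldn3 was 5.09-fold higher. Ion transport genes were lower for 6 of 13 members (median -0.32, 0.11 with free RNA subtracted, -0.064 in knockout cells with Xist) and lung transcription regulators for 5 of 19 (median -0.19, 0.0099 in male cells). MHC class II genes were higher for 3 of 5 (median 0.86), with Cd74 at 447 against 129 CPM; this median was -0.29 with doublets kept, -0.24 in knockout cells with Xist and 2.35 with free RNA subtracted. The other lists (NF-kB, TGF-beta, Wnt, Notch, BMP and FGF, YAP/TAZ target, basement membrane, hypoxia and glycolysis, interferon, lipid synthesis, lysosome, p53, stretch channel and tight junction) had medians between -0.086 and 0.31, and the sign of the lipid synthesis, lysosome, p53, stretch channel and tight junction medians depended on the scaling. Of all measured genes 53.2% were higher in the knockout, and 37.0% with the 20 most abundant genes left out of the total, which moved the median of all genes by -0.14 in log2.

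AT1-like cells of the ligation and wildtype libraries were compared to ask how AT1 expression differs after the airway is closed. The median of all measured genes was 0.20 in log2 here and 0.012 with TMM scaling, a shift of -0.19. List medians with TMM scaling therefore follow the main values in this and the next paragraph. Interferon response genes were higher: 9 of 15 measured members were at least 1.5-fold higher and 0 lower, with a median of 0.80 (0.61 with TMM), at percentile 100 of the random lists. In ligation ciliated-like cells 2 of 14 members were higher and 2 lower (median 0.32). In secretory-like cells, where most lists were higher, 4 of 6 were (median 0.86). In AT1-like cells Ifit3 was 2.58-fold (2.43 to 2.75) higher, its near-identical copy Ifit3b, with which it can share counts, 2.87-fold (2.51 to 3.28) higher, and the immunoproteasome subunit Psmb8 1.87-fold (1.72 to 2.05) higher. Immediate early and heat shock genes divided, with 11 of 22 higher and 4 lower (median 0.57, 0.38 with TMM; 14 of 22 higher, median 0.79 in ligation male cells and 4 of 22 higher, median 0.35 in those with Xist). Ier3, Ier2 and Nr4a1 were 2.46-fold (2.40 to 2.52), 2.20-fold (2.10 to 2.30) and 2.16-fold (2.01 to 2.31) higher, and the heat shock gene Hsph1 was 3.36-fold (2.98 to 3.78) lower. The immediate early and heat shock list had 7 of 22 higher and 5 lower (median 0.42) in ligation ciliated-like cells. In secretory-like cells 15 of 22 were higher and 2 lower (median 1.21).

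The AT1 list was near level in these cells, with 2 higher and 2 lower of 21 and a median of 0.23 (0.040 with TMM). Akap5 and the water channel Aqp5 were 1.69-fold and 1.67-fold higher, Ager 1.27-fold higher, and Spock2 and the caveolin Cav1 1.87-fold and 1.54-fold lower. Hopx, chosen here after its values were seen, was 1.17-fold (1.16 to 1.18) lower, at 7522 against 8805 CPM. Tight junction genes included Cldn18, the main alveolar claudin, 1.88-fold higher and F11r 1.77-fold higher, in a list with a median of 0.25 (0.063). The basement membrane list had a median of -0.12 (-0.31), and the collagen IV chains Col4a1 and Col4a2 were 1.55-fold and 1.66-fold lower. The Wnt, Notch, BMP and FGF list (0.22, 0.035) held Bmp4, 3.90-fold (3.49 to 4.37) higher, and 6 of 20 YAP/TAZ targets were higher (0.28, 0.089). Other large ratios were those of the noncoding RNA Snhg11 (5.99-fold higher, 5.46 to 6.58), the cytokine Tnfsf15 (5.47-fold higher, 4.61 to 6.54), the carboxylesterase Ces1d (3.61-fold higher, 3.37 to 3.88), Gsta3 (3.58-fold higher, 3.29 to 3.91) and Creg1 (3.03-fold higher, 2.91 to 3.16). Lower were Plod1, a collagen lysyl hydroxylase (7.55-fold, 6.64 to 8.61), Cox7a1 (6.42-fold, 5.36 to 7.74) and Crip1 (4.18-fold, 4.01 to 4.36).

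AT2 list members were lower in ligation AT1-like cells for 17 of 21 (median -1.99), with Scd1 16.9-fold, Slc34a2 5.39-fold and Sftpc 3.98-fold lower, and ciliated markers were higher for 8 of 9 (median 2.14). MHC class II genes were lower for 3 of 4 (median -1.14), H2-Aa being 2.80-fold lower. In ciliated-like cells the AT2 and MHC class II medians were -2.58 and -2.29. Wildtype and ligation cells were 52.9% and 5.69% AT2-like and 5.02% and 20.8% ciliated-like. With free RNA subtracted, the AT2 list median was -0.23, the MHC class II median 0.73, the secretory median -0.52 instead of 0.27, the ciliated median -1.77, and the log2 ratios of Slc34a2 and H2-Aa 1.36 and 0.65. With doublets kept, the AT2 list median was -0.84 and the MHC class II median -0.18. The transitional median was 0.14 here, -0.29 in male cells and 0.61 with clusters 1 and 7 joined, where 8 of 15 measured members were higher. The other lists (NF-kB, TGF-beta, actin and adhesion, hypoxia and glycolysis, ion transport, lipid synthesis, lung transcription regulator, lysosome, mesothelial, p53, stretch channel, secretory, transitional and unfolded protein) had medians between -0.025 and 1.03, and scaling set the sign of the TGF-beta, actin and adhesion, ion transport, lipid synthesis, lung transcription regulator, transitional and unfolded protein medians. Of all measured genes 73.2% were higher in the ligation library, 51.5% with TMM and 51.1% with DESeq2 size factors.

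Ligation and knockout AT1-like cells, both from lineage-traced mice, were set side by side to ask how these groups differ. All 14 measured transitional genes were at least 1.5-fold lower in the ligation library (median -1.49, -1.65 with TMM). Cluster 7 of the ligation library was kept out of this class because its leading genes held transitional markers, so the class itself was set in part by these genes. With clusters 1 and 7 joined, 13 of 15 members then measured were lower, and the median over the 14 was -0.94. Areg was 47.5-fold (37.3 to 61.4) lower, Sfn 30.3-fold (26.9 to 34.2) lower, Phlda1 9.60-fold (8.94 to 10.3) lower, Plaur 8.35-fold (7.34 to 9.51) lower, Thbs1 5.72-fold (5.30 to 6.16) lower and the small heat shock protein Hspb1 6.49-fold (6.30 to 6.69) lower. Hopx, chosen after its values were seen, was 5.20-fold (5.09 to 5.31) higher in ligation cells. Snhg11 was 136-fold (77.8 to 264) higher, the muscle-type fructose bisphosphatase Fbp2 74.5-fold (34.1 to 203) higher, Chst8 22.6-fold (14.1 to 39.0) higher, Efemp1, a fibulin, 9.58-fold (7.75 to 12) higher and Lpcat1, a surfactant lipid enzyme, 9.47-fold (8.35 to 10.8) higher.

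Between these 2 libraries the AT1 list had 5 members higher and 4 lower of 21 (median 0.25, 0.094 with TMM), with Akap5 2.05-fold higher and Ndnf and Igfbp2 2.67-fold and 2.43-fold lower. Lists with higher medians in the ligation cells were the Wnt, Notch, BMP and FGF list (0.50, 0.34 with TMM), with Id3 4.55-fold higher, the YAP/TAZ targets (0.40, 0.25), with Amotl2 2.85-fold higher, the lung transcription regulators (0.40, 0.25) and the interferon list (0.50, 0.34), with Ifit3 3.45-fold higher. Lower medians were those of MHC class II (-1.72, -1.87; -0.39 with doublets kept and -0.81 in cells with Xist), hypoxia and glycolysis (-0.47, -0.62), actin and adhesion (-0.37, -0.52), with Flna 3.81-fold lower, unfolded protein (-0.32, -0.47) and TGF-beta (-0.25, -0.40). The remaining lists (AT2, NF-kB, basement membrane, ciliated, immediate early and heat shock, ion transport, lipid synthesis, lysosome, mesothelial, p53, stretch channel, secretory and tight junction) lay between -1.26 and 0.58; the NF-kB, immediate early and heat shock, ion transport, lipid synthesis and stretch channel medians had a sign that depended on the scaling, and the ciliated and secretory medians were 0.12 and -0.041 with doublets kept and -3.73 and -3.82 with free RNA subtracted. The AT2 median, 0.39, was -0.38 with cells weighted equally, -0.17 with thinned cells, -0.078 with clusters 1 and 7 joined and 2.04 with free RNA subtracted. The median of all genes was 0.17 and shifted by -0.15 with TMM and -0.17 with DESeq2 size factors, and 64.6% of genes were higher in the ligation library (51.6% and 50.2% with those scalings).

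In AT1-like cells no more than 2 members of the basal, neuroendocrine, proliferating, macrophage, neutrophil, lymphoid, endothelial, mesenchymal and erythroid marker lists reached 50 UMIs in any comparison, so no median was formed for them. The same held there for the mesothelial list between knockout and wildtype. In AT2-like cells the same held for the basal, neuroendocrine, macrophage, neutrophil, lymphoid, endothelial, mesenchymal, mesothelial and erythroid lists, and for the proliferating list between ligation and knockout.

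The comparison of AT2-like cells between the knockout and wildtype libraries asks whether AT2-like cells of the traced mice differ from wildtype AT2 cells. Transitional genes were again higher in the knockout, 15 of 16 measured members, with a median of 2.39 above all random lists (1.54 in knockout cells with Xist), beside 1.38 in ciliated-like and 1.58 in secretory-like cells. Clu was 10.2-fold (9.51 to 11) higher, annexin A1 (Anxa1) 8.66-fold (8.17 to 9.19) higher, Sfn 8.62-fold (7.98 to 9.31) higher and galectin 3 (Lgals3) 6.25-fold (5.86 to 6.67) higher. The EGF receptor ligands Areg and Hbegf were 7.66-fold (7.39 to 7.94) and 6.92-fold (6.52 to 7.35) higher. Tnfrsf12a, the receptor of the cytokine TWEAK, was 7.95-fold (7.42 to 8.53) higher, Thbs1 6.18-fold (5.87 to 6.50) higher and Hspb1 5.49-fold (5.31 to 5.68) higher. Lipid and sterol synthesis genes were lower, 10 of 24 against 1 higher (median -0.50, below all random lists). Gpam, which starts glycerolipid synthesis, was 2.80-fold lower, and the desaturases Fads1, Fads2 and Scd2 were 2.45-fold, 2.56-fold and 2.31-fold lower. The lipid list was also lower in secretory-like knockout cells (7 of 19 lower, 2 higher, median -0.36). In ciliated-like cells 4 of 23 were lower and 3 higher (median -0.13).

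The AT2 list had 3 members higher and 7 lower of 22 (median -0.23, 0.022 in knockout cells with Xist). Scd1 was 2.17-fold lower and Bex2 3.07-fold lower, while the surfactant lectin Sftpd and lipocalin 2 (Lcn2) were 2.42-fold and 2.36-fold higher, and Sftpc stood at 191264 against 145088 CPM. The AT1 list was higher for 9 of 21 (median 0.49; 11 of 21 higher, median 0.67 in knockout male cells and 5 of 21 higher, median 0.16 in those with Xist), with Itgb6 4.35-fold, Igfbp2 4.28-fold and Ndnf 3.71-fold higher, whereas Cyp2b10 was 3.11-fold lower. Hopx, chosen after its values were seen, was 2.07-fold (1.84 to 2.33) lower, at 32.3 against 66.8 CPM. With free RNA subtracted its log2 ratio was 8.41. The wildtype level was then close to 0, at 2.91 UMIs, under the 3 UMIs used as a bound, so this ratio has no reliable size. Unfolded protein genes (8 of 16 higher, median 0.60) included Manf (2.59-fold) and Hspa5 (2.05-fold). Immediate early and heat shock genes (11 of 22, median 0.57, 0.20 in knockout cells with Xist) included Atf3 (2.47-fold) and the near-identical copies Hspa1a and Hspa1b (2.7-fold and 2.68-fold), which can share counts and whose log2 ratios were -0.29 and -0.46 in knockout cells with Xist. Interferon genes were higher for 6 of 12 (median 0.66), actin and adhesion genes for 11 of 24 (median 0.53; Flna 3.47-fold, Tpm4 2.45-fold), and MHC class II genes for 5 of 7 (median 0.76; H2-Eb1 3.35-fold).

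Matrix and signalling lists followed in knockout AT2-like cells. TGF-beta response genes were higher for 5 of 13 (median 0.53, 0.14 in knockout cells with Xist), Pmepa1 being 2.93-fold higher, and basement membrane genes for 7 of 16 (median 0.49), with the matrix protease Mmp14 8.29-fold (5.75 to 12.1) higher. Medians were 0.43 for hypoxia and glycolysis and 0.32 for YAP/TAZ targets (0.041 in cells with Xist). Among single genes, Stmn1, a microtubule regulator counted among the proliferating markers, was 5.36-fold (4.98 to 5.78) higher, and Pon1, Lifr, Trf and Nr1d1 were 3.90-fold, 3.10-fold, 2.92-fold and 2.89-fold lower. Ciliated (2.67) and secretory (1.05) medians were higher, beside the larger ciliated-like and secretory-like shares of that library, and were 0.28 and 1.72 with free RNA subtracted. The remaining lists (NF-kB, Wnt, Notch, BMP and FGF, ion transport, lung transcription regulator, lysosome, p53, stretch channel, proliferating and tight junction) had medians from -0.21 to 0.45, and the sign of the NF-kB, ion transport and lysosome medians turned on the scaling. Of all genes 51.8% were higher, and 38.2% with the 20 most abundant genes left out, which moved the median of all genes by -0.15.

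**Figure D2:**
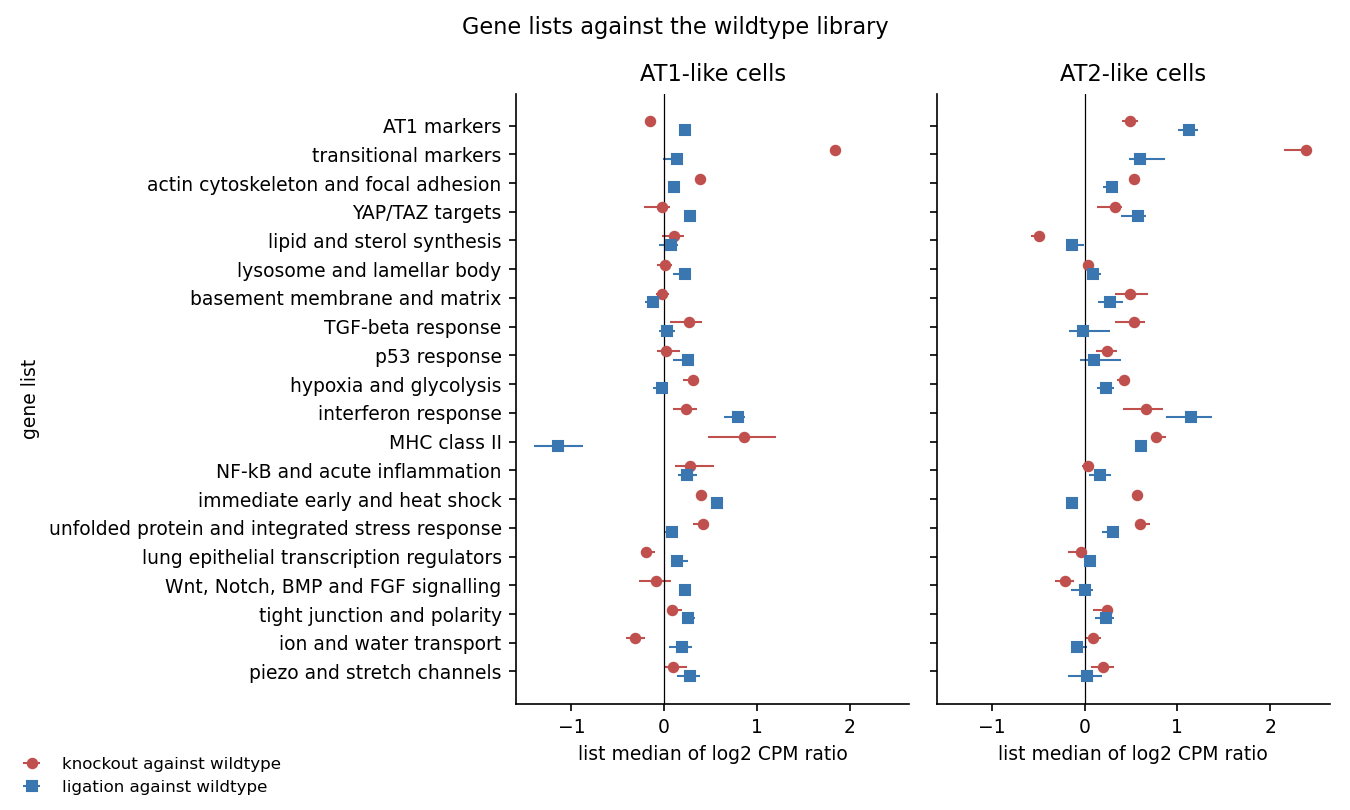
Median log2 CPM ratio to the wildtype library (horizontal axis) of the gene lists (vertical axis) in AT1-like and AT2-like cells, for the knockout (red circles) and ligation (blue squares) libraries; bars are 95% intervals for counting error, with 1 library per group. The transitional list lies at 1.85 and 2.39 in knockout AT1-like and AT2-like cells and at 0.14 and 0.60 in ligation cells, where the AT1-like value has the opposite sign under other scalings and is 0.61 with clusters 1 and 7 joined.

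AT2-like cells of the ligation and wildtype libraries were compared to ask whether AT2-like cells of the ligated, lineage-traced mice carry more AT1 transcripts. The AT1 list was higher for 16 of 21 measured members and lower for 0, with a median of 1.13 (0.96 with TMM, 0.97 with free RNA subtracted, 0.77 with doublets kept) above all random lists. In a comparison added after the data were seen, it was also higher outside this class, for 13 of 21 (median 0.63) in ciliated-like and 10 of 14 (median 0.80) in secretory-like cells. Most lists other than MHC class II and secretory markers were higher in secretory-like cells, such as tight junction (1.01) and lung transcription regulators (0.84). Scgb1a1 was lower there, at 487370 against 607740 CPM, which raises the CPM of other genes by construction. The value of 0.80 is thus not particular to AT1 genes. In AT2-like cells Hopx, which is not in the AT1 list, was 7.68-fold (7.26 to 8.12) higher. Of the list, Pdpn (podoplanin) was 7.95-fold (6.35 to 9.96), Rtkn2 7.16-fold (6.09 to 8.42) and Akap5 6.45-fold (5.91 to 7.03) higher. Igfbp2 was 4.93-fold (3.84 to 6.31) and Clic5 3.29-fold (3.05 to 3.54) higher. Their levels stayed below those of ligation AT1-like cells: Hopx was at 512 CPM here and 7522 CPM there, and Akap5 at 203 and 1815 CPM. AT2 genes were close to level, with 2 higher and 2 lower of 22; Sftpc stood at 174458 against 145088 CPM, Lcn2 was 3.17-fold higher and Scd1 3.12-fold lower.

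Interferon genes were higher in ligation AT2-like cells, 8 of 12 (median 1.15, 0.98 with TMM), including Ifit3 (10.6-fold, 7.41 to 15.2) and Psmb8 (2.82-fold), and so were MHC class II genes (4 of 7, median 0.60, 0.44), with H2-Ab1 1.81-fold and its transactivator Ciita 2.21-fold higher. Outside this class the interferon median was 0.32 in ciliated-like and 0.86 in secretory-like cells. Most lists were higher in ligation secretory-like cells, such as p53 (1.22) and hypoxia and glycolysis (1.23). The lower Scgb1a1 level there raises the CPM of other genes by construction. In AT2-like cells YAP/TAZ targets had 9 of 18 higher (median 0.57, 0.40), beside medians of 0.38 in ciliated-like and 1.04 in secretory-like cells. Transitional genes had 8 higher and 1 lower of 15 (median 0.60, 0.43; 4 of 14 higher, median 0.23 in male and 9 of 14 higher, median 0.82 in female ligation cells against wildtype male cells): Lgals3 and Krt7 were 2.99-fold and 2.87-fold higher and Areg 3.02-fold lower. The immediate early and heat shock list was lower for 6 and higher for 3 of 22 (median -0.14, -0.30), with Hspa1a and Hspa1b 5.80-fold and 6.15-fold and Hsph1 3.84-fold lower. Other large ratios belonged to Slc26a4, the anion exchanger pendrin (48.1-fold higher, 35.3 to 66.9), Retnla, a secretory marker (26.6-fold higher, 25.1 to 28.2), Cavin2 of caveolae (10.4-fold higher, 8.89 to 12.2), the small heat shock protein Cryab (9.71-fold higher, 8.83 to 10.7), Pmp22 (3.86-fold higher), Cd14, the lipopolysaccharide coreceptor (3.63-fold higher), and the matrix genes Tgm2 and Timp2 (4.43-fold and 3.37-fold higher). Retnla was higher in the ligation library in the other classes too, 20-fold in AT1-like, 10.1-fold in ciliated-like and 9.45-fold in secretory-like cells. The lipid synthesis median was -0.14 (-0.31), the secretory median 0.54 and the ciliated median 1.06, and the last 2 were -0.25 and -0.45 with free RNA subtracted. In male cells the unfolded protein and basement membrane medians were -0.18 and -0.020, instead of 0.30 and 0.28. The other lists (NF-kB, TGF-beta, Wnt, Notch, BMP and FGF, actin and adhesion, basement membrane, hypoxia and glycolysis, ion transport, lung transcription regulator, lysosome, p53, stretch channel, proliferating, tight junction and unfolded protein) had medians between -0.084 and 0.30, and the AT2, NF-kB, Wnt, Notch, BMP and FGF, lung transcription regulator, lysosome, p53 and stretch channel medians took either sign with the scaling. The median of all genes was 0.15, shifted by -0.17 with TMM, -0.15 with DESeq2 size factors and -0.11 without the 20 most abundant genes; 64.6% of genes were higher, against 47.8%, 49.5% and 54.0% with these scalings.

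How the AT2-like cells of the traced mice differ was asked between the ligation and knockout libraries. Transitional genes were lower in the ligation library for 13 of 16 members and higher for 0 (median -1.57, -1.70 with TMM; -0.86 in cells with Xist). Areg was 23.1-fold (19.9 to 27) lower, Sfn 7.97-fold (6.61 to 9.71) lower, Thbs1 15.8-fold (13.0 to 19.3) lower, Tnfrsf12a 5.52-fold (4.77 to 6.44) lower, and the heat shock genes Hspb1, Hspa1a and Hspa1b 9.28-fold (8.36 to 10.3), 15.7-fold (13.5 to 18.4) and 16.5-fold (14.0 to 19.7) lower. The AT1 median was 0.74 in ciliated-like and 0.70 in secretory-like cells, where most other lists were higher too, such as tight junction (0.76). Scgb1a1 stood at 487370 CPM in ligation against 632090 CPM in knockout secretory-like cells, which raises the CPM of other genes by construction. In AT2-like cells AT1 list genes were higher for 11 of 21 (median 0.83, 0.71 with TMM, 0.10 with doublets kept, 0.37 in male cells). Pdpn was 10.8-fold (7.31 to 16.3), Rtkn2 8.51-fold (6.56 to 11.2) and Akap5 3.59-fold higher. Hopx, which is not in this list, was 15.9-fold (14.1 to 17.9) higher. It was also 5.20-fold higher in AT1-like, 5.36-fold in secretory-like and 2.32-fold in ciliated-like cells. The Hopx ratio is thus not particular to AT2-like cells, although it was largest there among these classes. Lipid and sterol synthesis genes were higher for 9 of 24 (median 0.54, 0.41 with TMM, 0.16 in cells with Xist), beside medians of -0.016 in ciliated-like and 0.53 in secretory-like cells. In AT2-like cells Gpam was 3.35-fold and Fads1 2.21-fold higher. Transferrin (Trf) was 6.32-fold higher, Bex2 4.17-fold higher, Retnla 12.6-fold (11.7 to 13.6) higher and H2-Eb1 3.0-fold lower.

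Lower medians in ligation AT2-like cells were those of the TGF-beta list (-0.63, -0.75 with TMM, -0.14 in cells with Xist), the unfolded protein list (-0.42, -0.54), the immediate early and heat shock list (-0.37, -0.49), the actin and adhesion list (-0.34, -0.46) and the basement membrane list (-0.30, -0.42), and the YAP/TAZ median was 0.42 (0.30). The remaining lists (AT2, MHC class II, NF-kB, Wnt, Notch, BMP and FGF, ciliated, hypoxia and glycolysis, interferon, ion transport, lung transcription regulator, lysosome, p53, stretch channel, secretory and tight junction) lay between -0.46 and 0.25, and scaling decided the sign of the AT2, NF-kB, lysosome and tight junction medians. The interferon median, 0.24, was -0.027 in cells with Xist, the Wnt, Notch, BMP and FGF median, 0.18, was -0.084 with doublets kept, and the secretory and ciliated medians were -1.41 and -1.62 with free RNA subtracted. The median of all genes was 0.073, with shifts of -0.12 under TMM and -0.13 under DESeq2 size factors, and 57.2% of genes were higher (45.0% and 44.5% with these).

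Whether knockout and ligation cells differed from the wildtype library in the same genes was asked across genes, which are not independent replicates. In AT1-like cells the log2 ratios of 11445 genes had a Pearson correlation of 0.27 and a covariance of 0.118. Both comparisons share the wildtype library, and simulated libraries without any effect gave a correlation of 0.45 and a covariance of 0.0256. In AT2-like cells the correlation over 11986 genes was 0.33 and the covariance 0.144, against 0.15 and 0.0124 in simulation. With wildtype cells split at random between the comparisons the correlations were 0.19 and 0.28. Such a split leaves the library itself shared, so part of the excess over the simulated covariance can come from the 1 wildtype library.

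The presence of AT1 transcripts in AT2-like cells was asked cell by cell, with each cell thinned to 2000 UMIs and the shallower 240, 545 and 991 cells of the wildtype, knockout and ligation libraries left out. Over 10 AT1 genes fixed beforehand, the median share of AT2-like cells with a UMI was 8.19%, 7.89% and 26.0% in the wildtype, knockout and ligation libraries. The same median in ciliated-like cells, used as the background from free RNA, was 2.86%, 2.53% and 4.78%. Median depths before thinning were 17606, 10433 and 11264 UMIs in AT2-like and 10340, 7533 and 8438.5 UMIs in ciliated-like cells, and the unthinned medians in AT2-like cells were 41.9%, 27.1% and 69.7%. Akap5 was found in 5.31%, 9.87% and 28.6% of AT2-like cells and in 2.86%, 2.09% and 4.67% of ciliated-like cells (unthinned, AT2-like: 31.4%, 32.3% and 73.2%). For Rtkn2 the AT2-like shares were 1.98%, 1.66% and 9.38%, the ciliated-like shares 1.43%, 0.664% and 2.92% and the unthinned AT2-like shares 12.8%, 5.82% and 34.4%. Hopx was found in 11.1%, 5.92% and 52.1% of AT2-like and 49.0%, 32.4% and 58.5% of ciliated-like cells, so its AT2-like shares lay below the ciliated-like ones (unthinned, AT2-like: 52.5%, 21.8% and 86.7%). Subtracting free RNA at the estimated shares left 348 of 403 CPM of Hopx in wildtype and 207 of 210 CPM in knockout ciliated-like cells. Ciliated-like cells are thus no background from free RNA for this gene.

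**Figure D3:**
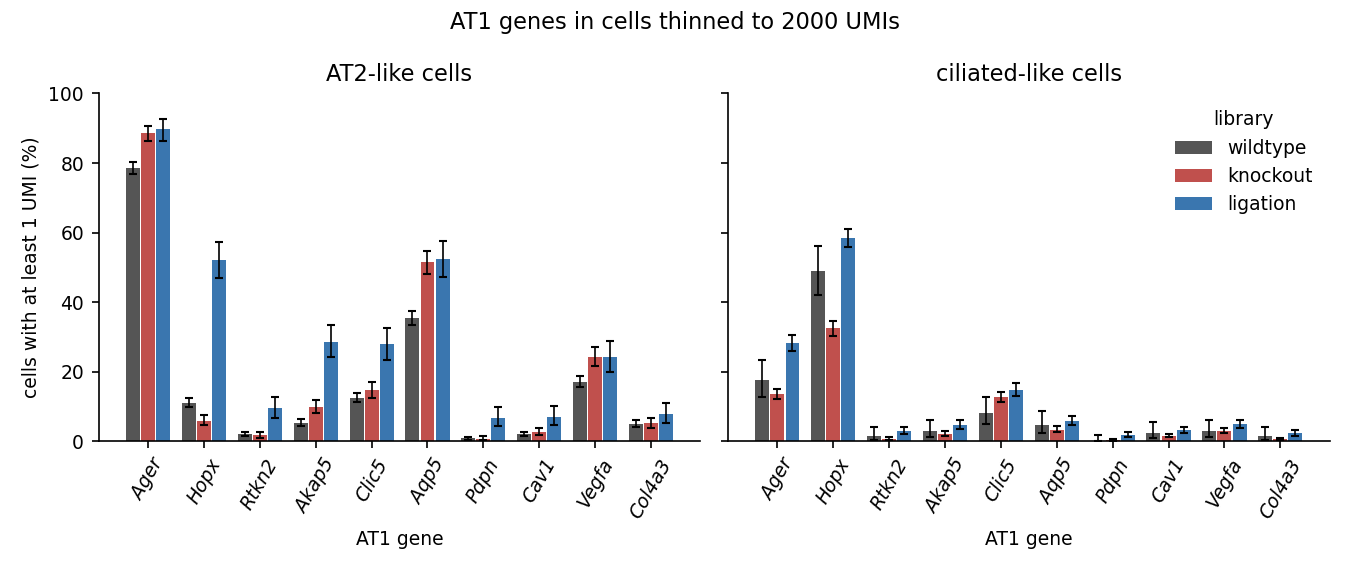
Share of cells with a UMI (vertical axis, percent, after thinning to 2000 UMIs) of each of 10 AT1 genes (horizontal axis) in AT2-like and in ciliated-like cells of the 3 libraries; error bars are exact 95% binomial intervals for counting error. In the ligation library Akap5 was found in 28.6% of AT2-like against 4.67% of ciliated-like cells.

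In the opposite direction, 10 AT2 genes had a median share of 3.25%, 1.17% and 0.489% of AT1-like cells and 5.48%, 1.28% and 0.584% of ciliated-like cells, at median depths of 11646, 8508 and 6353 UMIs in AT1-like cells (unthinned, AT1-like: 13.3%, 4.02% and 1.56%). These AT1-like medians lay below the ciliated-like background. Sftpc UMIs were found in 96.4%, 76.9% and 54.5% of AT1-like and 96.7%, 77.5% and 43.7% of ciliated-like cells (unthinned, AT1-like: 99.9%, 98.8% and 88.9%). Slc34a2, the AT2 phosphate transporter, was found in 7.18%, 1.17% and 1.51% of AT1-like and 9.05%, 1.89% and 0.803% of ciliated-like cells (unthinned, AT1-like: 30.4%, 5.45% and 3.40%), so that both genes lay above the ciliated-like share in the ligation library alone. Lpcat1 stood apart in the ligation library, with 50.6% of AT1-like and 2.19% of ciliated-like cells (unthinned, AT1-like: 84.3%); it was singled out after its values were seen.

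Cells with UMIs of at least 3 of the 10 AT1 and at least 3 of the 10 AT2 genes were 442 of 3239 AT1-like or AT2-like cells in the wildtype, 13.6% (12.5 to 14.9), 263 of 1734 in the knockout, 15.2% (13.5 to 16.9), and 236 of 2838 in the ligation library, 8.32% (7.33 to 9.39). Without thinning these shares were 76.8%, 49.7% and 16.8%. Such a class is a range of a score and not a cell type, and free RNA and undetected doublets also give such cells. Within AT2-like cells the shares were 18.5%, 27.1% and 57.3%. Requiring at least 6 AT1 genes, a bound chosen after the data were seen, left 4 of 2223, 4 of 963 and 37 of 384 AT2-like cells. Cells with UMIs of at least 3 proliferating genes, such as Mki67 and Top2a, were 4 of 3248 AT1-like, AT2-like or proliferating-like cells in the wildtype and 25 of 1766 in the knockout, shares of 0.123% (0.0336 to 0.315) and 1.42% (0.918 to 2.08), and 0.768% and 2.77% without thinning. In the ligation library they were 0 of 2838, which allows a share of up to 0.106%, and the unthinned count was 0 of 2912. The proliferating-like class, with 9, 32 and 0 cells, was named from the same genes, so these shares follow in part from that naming. Whether its cells were alveolar was not tested. In ciliated-like cells 5 of 6 proliferating members were also higher in the knockout than in the wildtype library (median 2.33).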

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

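The tests on cluster 7 were chosen only after its composition had been seen. Of the clusters that entered no class, 3 held shares with intervals above that of the wildtype library. Cluster 1 held 14.2% of knockout and 15.7% of ligation cells, cluster 7 held 13.7% of ligation cells and cluster 16 held 1.62% of ligation cells, beside 7.66%, 0.167% and 0% of wildtype cells in these clusters (the last up to 0.0714%). Cells of cluster 1 were shallow, with wildtype, knockout and ligation medians of 2056, 1555 and 1432 UMIs. All cells kept had medians of 14464, 7981 and 6354 UMIs. For 3 lists the medians of ligation over wildtype had opposite signs in AT1-like and AT2-like cells, clear of 0 by counting error and past 0.5 in log2 in at least 1 class; other lists had opposite signs with smaller values, such as basement membrane (-0.12 and 0.28). AT1-like minus AT2-like, the medians differed by -2.12 for the AT2 list, -1.74 for MHC class II and 0.71 for immediate early and heat shock genes in log2, and these differences were not tested. The opposite signs did not hold in every setting: the AT2 list median of AT2-like cells was -0.044 with TMM, and the MHC class II median of AT1-like cells was 0.73 with free RNA subtracted.

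Cluster 7 of the ligation library held 776 cells with Xist alone and 7 with Y-linked UMIs alone, although neither Xist nor Y-linked genes took part in the clustering. The skew was not particular to cluster 7, since cluster 16 of this library held 99 and 1 such cells. Y-linked UMIs missed at low depth are argued against by cluster 8, where 48.2% of cells (44.9 to 51.5) had Y-linked UMIs alone at a median of 6686 UMIs, beside 6352.5 in cluster 7. A state that ligation gave alike to every pooled animal is also argued against: of the cells of cluster 7 and the AT1-like class, 1.36% of male cells (0.548 to 2.78) and 38.0% of female cells (35.9 to 40.1) lay in cluster 7. The cluster may thus come from 1 or some of the pooled animals, as a hypothesis found and tested on the same data. Whether sex, a single animal, or how ligation, sort or dissociation went in it lies behind this was not tested.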

How the results depend on the processing

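Using clusters 1 and 7, cells of 1 sex or 6 AT1 genes was chosen after the data were seen, as was the list singled out per comparison (transitional, interferon in AT1-like ligation/wildtype, AT1 in AT2-like ligation/wildtype). All other alternatives were planned. No paired analysis was possible because each group is 1 library. Sex-matched values in every library, planned for at least 100 cells of each sex, were not run, since the wildtype library held 14 cells with Xist alone. Over all alternatives the AT2-like share of both classes lay at 62.1 to 68.8% (wildtype), 39.4 to 56.9% (knockout) and 7.84 to 13.8% (ligation), so its order was kept, and the singled-out medians kept their sign. Of 1702 alternative list medians 1150 lay within the counting interval of the main value, 546 outside it and 6 had the opposite sign from a main value past 1.5-fold. For named genes these were 1209, 716 and 6 of 1931, for class shares 43 within and 32 outside, and for shares of cells with a UMI 9 and 60. Depth limits the wildtype secretory-like and ciliated-like sums most, and among alveolar sums those of ligation AT2-like cells. Unless construction shows it, the cause was not tested.

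Without a cell filter the AT2-like share of both classes was 62.4% (wildtype), 51.3% (knockout) and 11% (ligation), the AT1-like share was 12.8% (knockout) and 42.4% (ligation) and the AT2-like share was 38.6% (wildtype) and 13.5% (knockout). With the strict cell filter the AT2-like share of both classes was 65.9% (wildtype), the AT1-like share was 31.5% (wildtype), 18.5% (knockout) and 44.8% (ligation) and the AT2-like share was 61.1% (wildtype), 24.4% (knockout) and 6.87% (ligation). With thinned cells the AT2-like share of both classes was 51.2% (knockout) and 11.3% (ligation), the AT1-like share was 29.9% (wildtype), 21.2% (knockout) and 55.3% (ligation) and the AT2-like share was 62.3% (wildtype), 22.3% (knockout) and 7.04% (ligation). With doublets kept the AT2-like share of both classes was 11.4% (ligation) and the AT1-like share was 40.8% (ligation). With the lists kept in the clustering the AT2-like share of both classes was 11.4% (ligation), the AT1-like share was 45.0% (ligation) and the AT2-like share was 54.7% (wildtype). At resolution 0.5 the AT2-like share of both classes was 11.2% (ligation) and the AT1-like share was 45.0% (ligation). With clusters 1 and 7 joined the AT2-like share of both classes was 62.1% (wildtype), 39.4% (knockout) and 7.84% (ligation).

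With TMM factors the transitional median was 1.81 (AT1-like, knockout/wildtype) and -1.65 (AT1-like, ligation/knockout), the interferon median was 0.61 (AT1-like, ligation/wildtype) and the AT1 median was 0.96 (AT2-like, ligation/wildtype), and of the log2 ratios, that of Cdc42 was -0.27 (AT1-like, ligation/wildtype), -0.28 (AT1-like, ligation/knockout), 0.18 (AT2-like, ligation/wildtype) and -0.32 (AT2-like, ligation/knockout). With DESeq2 size factors the interferon median was 0.60 (AT1-like, ligation/wildtype), the transitional median was -1.66 (AT1-like, ligation/knockout) and the AT1 median was 0.98 (AT2-like, ligation/wildtype), and of the log2 ratios, that of Cdc42 was -0.27 (AT1-like, ligation/wildtype), -0.30 (AT1-like, ligation/knockout), 0.19 (AT2-like, ligation/wildtype) and -0.33 (AT2-like, ligation/knockout). With the 20 most abundant genes left out of the total the transitional median was 1.71 (AT1-like, knockout/wildtype) and -1.43 (AT1-like, ligation/knockout), and of the log2 ratios, that of Cdc42 was -0.087 (AT1-like, knockout/wildtype), -0.16 (AT1-like, ligation/wildtype), -0.071 (AT1-like, ligation/knockout), 0.39 (AT2-like, knockout/wildtype) and 0.23 (AT2-like, ligation/wildtype). With a pseudocount of 1 CPM and no minimum the transitional median was 1.59 (AT1-like, knockout/wildtype), -1.42 (AT1-like, ligation/knockout), 1.93 (AT2-like, knockout/wildtype) and -1.27 (AT2-like, ligation/knockout) and the interferon median was 0.52 (AT1-like, ligation/wildtype). With cells weighted equally the transitional median was 1.79 (AT1-like, knockout/wildtype) and -1.60 (AT1-like, ligation/knockout) and the interferon median was 0.63 (AT1-like, ligation/wildtype), and of the log2 ratios, that of Cdc42 was -0.14 (AT1-like, ligation/wildtype) and -0.19 (AT1-like, ligation/knockout). With thinned cells the transitional median was 1.81 (AT1-like, knockout/wildtype) and -1.65 (AT1-like, ligation/knockout), and of the log2 ratios, that of Cdc42 was -0.16 (AT1-like, ligation/wildtype), -0.19 (AT1-like, ligation/knockout), -0.059 (AT2-like, ligation/wildtype) and -0.64 (AT2-like, ligation/knockout). With doublets kept the transitional median was 1.93 (AT1-like, knockout/wildtype), -1.40 (AT1-like, ligation/knockout) and 2.47 (AT2-like, knockout/wildtype), the MHC class II median was -0.29 (AT1-like, knockout/wildtype), the ciliated median was 0.12 (AT1-like, ligation/knockout) and the AT1 median was 0.77 (AT2-like, ligation/wildtype), and of the log2 ratios, that of Cdc42 was 0.11 (AT1-like, knockout/wildtype). With free RNA subtracted the ciliated median was -1.77 (AT1-like, ligation/wildtype) and -0.45 (AT2-like, ligation/wildtype), the MHC class II median was 0.73 (AT1-like, ligation/wildtype), the transitional median was 2.54 (AT2-like, knockout/wildtype) and the AT1 median was 0.97 (AT2-like, ligation/wildtype), and of the log2 ratios, that of Sftpc was 0.15 (AT1-like, knockout/wildtype), that of Slc34a2 was 1.36 (AT1-like, ligation/wildtype), that of H2-Aa was 0.65 (AT1-like, ligation/wildtype) and that of Hopx was 8.41 (AT2-like, knockout/wildtype, with 2.91 wildtype UMIs left). With the lists kept in the clustering the transitional median was -1.56 (AT1-like, ligation/knockout). With clusters 1 and 7 joined the transitional median was 1.81 (AT1-like, knockout/wildtype) and -0.94 (AT1-like, ligation/knockout), and of the log2 ratios, that of Cdc42 was 0.12 (AT1-like, knockout/wildtype) and -0.012 (AT1-like, ligation/wildtype). In male cells alone the transitional median was 2.16 (AT1-like, knockout/wildtype), -1.81 (AT1-like, ligation/knockout), 2.64 (AT2-like, knockout/wildtype) and -2.18 (AT2-like, ligation/knockout) and the AT1 median was 0.96 (AT2-like, ligation/wildtype), and of the log2 ratios, that of Cdc42 was -0.18 (AT1-like, ligation/knockout). In female cells against male wildtype cells the transitional median was 1.68 (AT1-like, knockout/wildtype), -1.35 (AT1-like, ligation/knockout), 1.54 (AT2-like, knockout/wildtype) and -0.86 (AT2-like, ligation/knockout) and the MHC class II median was -0.24 (AT1-like, knockout/wildtype), and of the log2 ratios, that of Cdc42 was -0.032 (AT1-like, ligation/wildtype), 0.40 (AT2-like, knockout/wildtype) and -0.032 (AT2-like, ligation/knockout), that of Hspa1a was -0.29 (AT2-like, knockout/wildtype) and that of Hspa1b was -0.46 (AT2-like, knockout/wildtype).

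Without thinning, alveolar cells with both lists were 76.8% (wildtype), 49.7% (knockout) and 16.8% (ligation), cells with cycling genes 0.768% (wildtype) and 2.77% (knockout), the AT1 gene median in AT2-like cells 41.9% (wildtype), 27.1% (knockout) and 69.7% (ligation) and the AT2 gene median in AT1-like cells 13.3% (wildtype), 4.02% (knockout) and 1.56% (ligation). Thinned to 1000 UMIs, these were 3.88% (wildtype), 4.67% (knockout) and 4.70% (ligation) for both lists, 4.5% (wildtype), 4.47% (knockout) and 14.6% (ligation) for AT1 genes and 1.95% (wildtype) for AT2 genes. Fewer UMIs per cell, or more genes asked for, lower such shares by construction: with at least 4 genes of each list 4.01% (wildtype), 3.58% (knockout) and 4.69% (ligation) of alveolar cells passed, and with 6 AT1 and 3 AT2 genes 0.988% (wildtype), 0.346% (knockout) and 1.87% (ligation). At least 2 cycling genes were found in 0.369% (wildtype) and 2.89% (knockout). The correlation of knockout and ligation ratios was 0.20 (AT1-like) and 0.31 (AT2-like) over genes with at least 200 UMIs, and 0.19 and 0.28 with split wildtype cells. Interferon members higher in ligation AT1-like cells numbered 9 at 1.5-fold and 3 at 2-fold, a stricter bound.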

Other observations

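The tests of scaling and depth, of the whole library and of the AT1 list for Hopx, and those of free RNA and doublets for AT1 transcripts, were chosen only after the result was seen, as were the genes and clusters described next. Within the ligation library, clusters 3 (1411 cells) and 8 (899 cells) were named AT1-like, and cluster 7 (926 cells) had AT1 as its best list but stayed unnamed, since its leading genes held 0 AT1 markers and 2 transitional ones, Hbegf and Lgals3. Higher transitional genes in cluster 7 were thus in part known before it was compared with cluster 3. Transitional genes were higher in cluster 7 than in cluster 3 for 12 of 14 measured members (median log2 ratio 1.47, 1.44 to 1.51). Sfn was 6.49-fold (5.53 to 7.64) higher, the cell cycle inhibitor Cdkn1a 3.56-fold (3.27 to 3.89) higher and the keratin Krt8 3.07-fold (2.97 to 3.17) higher. AT2 genes were higher for 7 of 11 (median 0.71) and TGF-beta response genes for 4 of 10 (median 0.41). The AT1 list was lower by its median of -0.25, with Ager at 22043 CPM in cluster 7 and 29035 CPM in cluster 3, and so were the basement membrane (-0.28) and interferon (-0.21) lists.

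Clusters 3 and 8 also differed. Cells with Xist alone and with Y-linked UMIs alone numbered 1135 and 41 in cluster 3 and 58 and 433 in cluster 8 of the ligation library. Immediate early and heat shock genes were lower in cluster 3 for 6 of 22 (median -0.31), and signalling genes of the Wnt, Notch, BMP and FGF list had a median of -0.28, with Id1 at 70.9 CPM in cluster 3 and 193 CPM in cluster 8. NF-kB genes (0.41), transitional genes (0.43) and interferon genes (0.22) had higher medians in cluster 3. Clu was 3.37-fold (2.64 to 4.36) higher there.

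Hopx was lower in AT1-like cells of the knockout library than of the wildtype library. Sex differences of the pools are argued against by male cells alone, where the log2 ratio was -2.67, and scaling and depth by the highest ratio over the scaling, thinning, doublet and free RNA settings, -2.54. Within AT1-like cells the AT1 list median was -0.15, beside -2.61 for Hopx. These cells were named from the same list, so this median cannot decide whether the AT1 programme as a whole was lower. A lower Hopx level in the whole knockout library stays open, since log2 ratios were -1.81 (-2.04 to -1.59) in secretory-like and -0.94 in ciliated-like cells, beside -2.61 in AT1-like cells. Free RNA from AT1 cells can carry part of this: with it subtracted the secretory-like and ciliated-like ratios were -1.16 and -0.75. The AT2-like ratio went from -1.05 to 8.41, but 2.91 wildtype UMIs were left there, under the 3 UMIs used as a bound. It therefore decides nothing here. Loss of Cdc42, the sort, single animals and the number of altered Hopx alleles, since the strains carry Hopx-creERT2 per the labels, stay open and were not tested.

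AT1 transcripts were higher in AT2-like cells of the ligation library than of the wildtype library. A single animal whose cells alone carried them is argued against by the AT1 list medians in male and female cells, 0.96 (0.84 to 1.12) and 1.17. Free RNA is shared by all cells of the pool. If it carried the excess over wildtype, these medians could not exclude a single animal as its source. Free RNA as the source of all these transcripts is argued against by ciliated-like cells of the library, which held the AT1 genes at a median of 0.33 times the AT2-like level. Resampling the 21 genes gave a range of 0.238 to 0.521, a spread over genes and not counting error. Single genes ranged from 0.0828 to 16.1. As the source of the excess over wildtype free RNA stays open. With free RNA subtracted at the estimated shares the AT1 list median was 0.97, but over the range of shares that single genes gave this median went from 0.32 to 1.28. The AT1 list was higher than in wildtype in ciliated-like cells too (0.63). Undetected doublets stay open too: of 37 AT2-like cells with at least 6 AT1 and 3 AT2 genes 0 had UMIs of both sexes (up to 8.11% by the limit of 3 counts and 9.49% by the exact interval), beside 18 of 125 removed doublets, 14.4% (8.76 to 21.8), so the choice of limit decides whether the ranges overlap, and the doublets were deeper, with median UMIs of 18000 against 11967. Descent of some AT2-like cells from AT1 cells after ligation could add such transcripts, but this cannot be told apart here from doublets or from free RNA as the source of the excess, and age, which differs by the labels, and sort stay open as well.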
